A study of Mus musculus with 54 samples.

How the data were processed

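RNA was measured by sequencing in 54 mouse livers: 3 genotypes, 6 harvest times and 3 mice per genotype and time. Per the labels' protocols, the libraries were stranded, made from total RNA after removal of ribosomal RNA, and sequenced from one end. The submitters' processing notes name CASAVA 1.8.2 and the genome build mm10, without their role. The aligner, the quantification tool and the gene annotation are not given in the sources used here.

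The authors deposited one table with a value per gene and library. Its unit is not named; from the values it was taken as FPKM made by the authors, that is, scaled by gene length and library depth. At low values, the share at the most frequent value was 14.6% ± 2.36 (SD, n = 54 libraries) after multiplication by transcript length and 5.29% ± 0.667 without it. TPM with genes removed is not excluded. From those 1-read steps the depth was about 31.1 ± 4.18 M reads per library (mega reads; SD, n = 54), between 25.8 and 43.3 M reads. Part of the low values, 12.7% ± 3.15 (SD, n = 54), lay below 0.5 of a step, which whole reads do not give, so whole reads were not recovered. Because the values are not counts, no count model was used, and no interval for counting error is given. The sums of the FPKM values lay between 274353 and 419402.

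Values were analysed as log2(FPKM + 1), for the 11759 genes with a mean of at least 0.5 over all libraries; 6320 genes fell below that. Fold changes are on this scale, which understates the change of low genes. One model in limma 3.58.1 (R 4.3.3; empirical Bayes with an intensity trend) held a mean and a 24 h cosine and sine for each genotype, with one spread per gene shared by the genotypes. Mean level contrasts compared the genotype means of these log2 values, which a change in swing alone can shift without a change in the mean FPKM. A rhythm was an F test of the cosine and sine of one genotype, and a rhythm difference the F test of their difference between 2 genotypes. P-values were adjusted by the Benjamini-Hochberg method in each test, with a threshold of 0.05. Peak-to-trough fold and peak time came from the cosine. Gene lists were tested with camera in limma, with the correlation between genes estimated from the data, adjusted over all lists and contrasts; lists with fewer than 3 measured genes were not tested. List counts are over all genes tested, and the count adjusted over the list alone is given where it differed. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the figures.

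The tests, the gene lists, the other settings and the rule for named genes were fixed before the data were examined. Named were all measured clock list members; per mean level contrast the 10 highest and 10 lowest fold changes past the threshold with a mean of at least 1 in the higher genotype and one sign at all 6 harvest times; per genotype the 10 largest peak-to-trough folds past the threshold with a mean of at least 1; per rhythm difference the 10 smallest p-values; and per list up to 4 members with the smallest p-values. Predicted genes and pseudogenes were left out of all but the first and last of these, and the text leaves out some for length. Some genes that the rule takes are not reported here. Peak times shared by WT and Liver-RE were compared over genes called in both with a peak-to-trough of at least 1.5 in both.

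The functions were tested on simulated data for the 11759 genes, in 10 sets with 200 changed genes. With independent genes, a KO vs WT log2 fold change of 0.5 was recovered for 95.0% of changed genes, with 6.4% false calls. In KO, rhythms with a peak-to-trough of 1.5 were recovered for 75.4% and of 2 for 91.8%; in Liver-RE the values were 67.8% and 91.6%. False calls were 7.9% in WT, 20.2% in KO and 20.7% in Liver-RE, in the simulation, where each genotype had its own spread while the model shares one per gene; the threshold was 0.05. With whole residual libraries drawn with replacement, which keeps the correlation between genes, up to 3206 genes were falsely rhythmic in KO in 1 set, with a median of 12. The highest and median numbers were 1233 and 22.5 for rhythms in Liver-RE, 1018 and 10.5 for rhythms in WT, and 411 and 2.5 for the level KO vs WT. Rhythm counts were therefore also set against shuffled harvest times.

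Alternatives were the replicate number as a block, a pseudocount of 0.1, no filter, quantile normalization, a mean per group as the fitted terms, robust empirical Bayes, each library left out in turn, and fits of only the genotypes concerned. With group means the spread came from within the groups, while the rhythm tests stayed those of the 24 h cosine and sine. For rhythms, a rank test over 12 phases and an F test between the 6 times were also run. After the data were seen, 2 libraries with clock genes out of phase were also left out together, and camera was run with a preset correlation. Coordinates are from RefSeq on GRCm38.p6, the assembly that mm10 names, matched by symbol. Strand use in the counting is not stated, so overlapping and antisense genes, and near-identical family members such as those of the Cyp2a, Cyp3a, Sult2a and Mup families, carry uncertain values.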

Results

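The study asked how far the liver clock runs on its own. Livers came from female C57BL/6J mice that were wild type (WT), lacked BMAL1 (KO), or lacked BMAL1 except for its reconstitution in the liver (Liver-RE). BMAL1, encoded by Arntl, is a transcription factor at the core of the circadian clock. Mice were fed freely under a light and dark cycle, and 3 per genotype were taken at each of ZT0, 4, 8, 12, 16 and 20, where ZT counts hours from lights on. Each genotype thus had 18 libraries. The depth, estimated from the smallest steps in the values, was 32.4 ± 4.07 M reads (mega reads) in WT, 30.5 ± 3.52 M reads in KO and 30.5 ± 4.80 M reads in Liver-RE (SD, n = 18).

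Arntl (chromosome 7, 113178471 to 113314126, GRCm38) cycled in WT, was flat in the libraries labelled KO, and cycled in Liver-RE. In WT its mean was 11.6 ± 0.376 FPKM at ZT0 and 0.436 ± 0.0764 at ZT12 (SD, n = 3). The cosine fitted to log2(FPKM + 1) over all WT libraries had a peak-to-trough fold of 8.11 and a peak at ZT22.78. In KO every group mean lay between 7.03 ± 1.14 at ZT0 and 8.69 ± 0.0508 at ZT16 (SD, n = 3). In Liver-RE Arntl was lowest at ZT8, 1.40 ± 0.525, and highest at ZT16, 9.46 ± 1.60 (SD, n = 3). Its mean log2 level over the day was higher in KO than in WT, log2 fold change 0.67, limma adjusted p = 0.00185. The loss of the deep trough alone can raise such a mean. A value for the whole gene therefore did not check the KO label, and which part of the gene the allele changes is not stated in the sources used here. At ZT8, WT replicate 2 had an Arntl value of 10.6 FPKM, against 0.414 and 0.563 in the other replicates of that group.

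**Figure D1:**
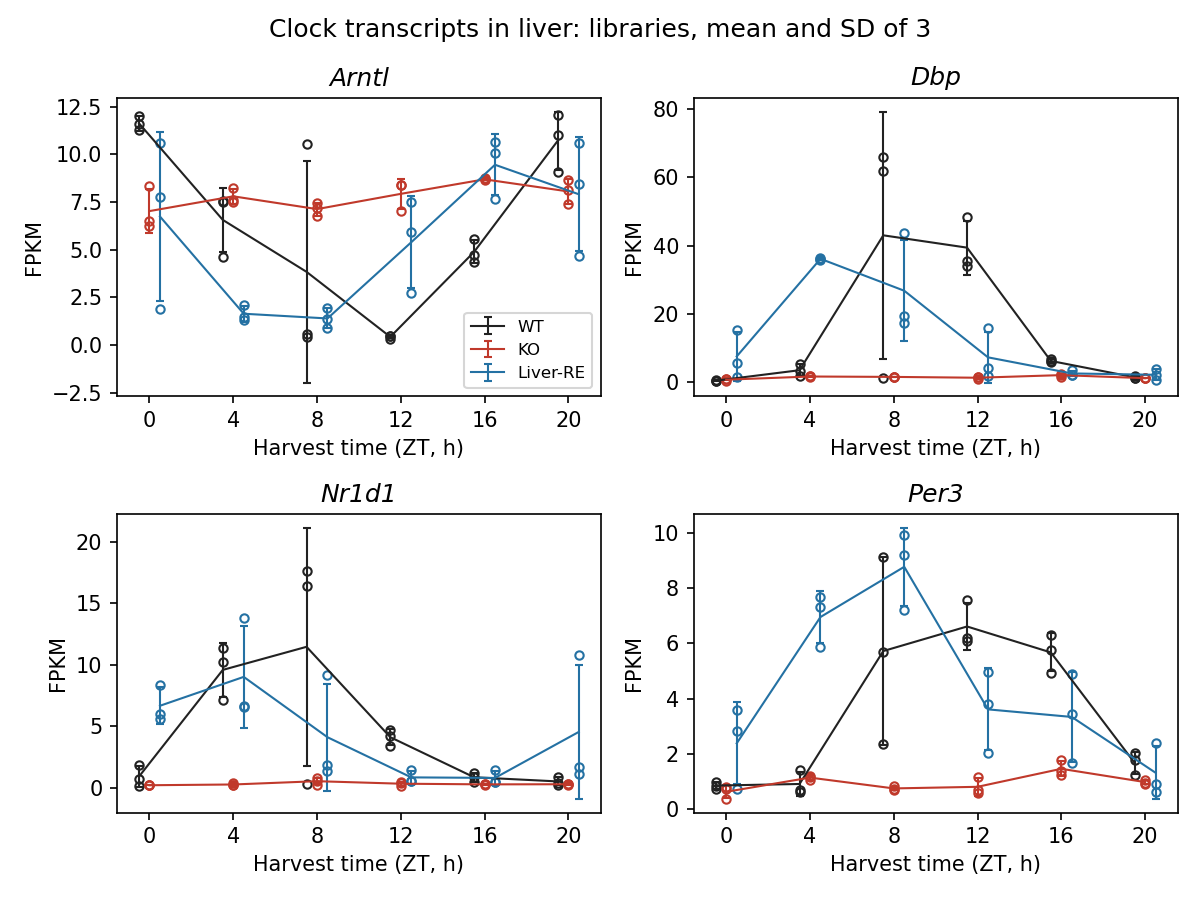
FPKM of Arntl, Dbp, Nr1d1 and Per3 against harvest time in h (ZT); open circles are libraries, lines join means and bars are the SD of 3 libraries, by genotype. The peak-to-trough of Arntl, from the cosine fitted to log2(FPKM + 1), was 8.11 in WT and 4.64 in Liver-RE, against 1.15 in KO.

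The first comparison asked which transcripts cycle in each genotype. In WT, 2760 of 11759 genes had a 24 h rhythm, 1095 of them with a peak-to-trough of at least 1.5. The list of core clock genes and direct outputs led: 19 of 23 measured members were rhythmic, and 19 when adjusted over the list alone. Among the named genes Dbp, a transcription factor driven directly by the clock, had the largest swing, 24.8-fold with a peak at ZT10.86. Tsku, a secreted protein, followed with 13.2-fold at ZT14.14, Alas1, the rate-limiting enzyme of heme synthesis, with 9.09-fold at ZT12.5, and Cyp2a5 with 8.15-fold at ZT13.06. Nr1d1, a heme-binding repressor of Arntl, peaked at ZT7.25 with 7.82-fold, and Usp2 at ZT13.27 with 7.91-fold. Among the other lists, 16 of 26 cholesterol synthesis genes were rhythmic (19 adjusted over the list alone), among them Insig2, 5.68-fold at ZT23.52, and Hmgcs1, 5.07-fold at ZT3.88. Of the glycogen and glucose genes 14 of 27 were rhythmic (16 over the list alone), with Gys2, liver glycogen synthase, at 4.88-fold and ZT12.39. Of the interferon response genes 12 of 22 were rhythmic (15 over the list alone), with Isg15 at 2.35-fold and ZT4.72. Of the bile acid genes 11 of 18 were rhythmic, with Hsd3b7 at 4.65-fold and ZT2.3. The glucocorticoid-responsive list had 10 of 16 members rhythmic (11 over the list alone). The rank test over 12 phases called 1696 genes in WT.

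In KO, limma called 0 genes rhythmic. At an unadjusted p under 0.05 there were 1105 genes, where chance gives 588, and the smallest adjusted p was 0.0542. The rank test and the F test between 6 harvest times also called 0. Leaving out 1 library at a time gave between 0 and 3 genes, the 3 without KO ZT20 replicate 2 and 1 without any of 12 other libraries. Adjusted over the list alone, 1 gene passed in NAD metabolism, 1 in urea cycle and amino acid metabolism and 2 of 4 adipocyte markers. Dbp had a peak-to-trough of 1.32 in KO, Nr1d1 1.17, Per3 1.18 and Usp2 1.05. Over the 1095 genes with a rhythm of at least 1.5 in WT, the median peak-to-trough was 1.76 in WT, 1.18 in KO and 1.36 in Liver-RE. With shuffled harvest times it was 1.16 in KO, at most 1.21 over 20 shuffles, and 1.21 in Liver-RE. These genes were chosen on their WT rhythm, which raises the WT value. In the direct test of the difference, 915 genes differed in rhythm between KO and WT, 816 of them rhythmic in WT. Of the 23 clock genes 17 differed (18 adjusted over the list alone). Those with the smallest p included Loxl4 (adjusted p = 7.84e-07), Ndrg1, Tef, Clpx, Lgals9 and Nampt, the rate-limiting enzyme of NAD salvage. Nampt had a peak-to-trough of 3.55 in WT and 1.22 in KO, where it was not called rhythmic. Leaving out WT ZT12 replicate 3 lowered the count of rhythm differences to 568, and leaving out WT ZT8 replicate 2 raised it to 1133.

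In Liver-RE, 449 genes were rhythmic, 245 of them with a peak-to-trough of at least 1.5. The core clock list again led with 14 of 23 members, 17 when adjusted over the list alone. Dbp cycled 13.4-fold with a peak at ZT5.88, Nr1d1 6.18-fold at ZT2.18, Arntl 4.64-fold at ZT18.09, Per3 3.79-fold at ZT7.5 and Nfil3 3.29-fold at ZT16.43. Per1 (1.16-fold), Cry2 (1.33-fold) and Hlf (1.17-fold), rhythmic in WT, did not pass the test in Liver-RE. Outside the clock list, Igfbp1, a binding protein of insulin-like growth factors, cycled 8.87-fold, the cell cycle inhibitor Cdkn1a 5.59-fold, Pdk4 4.44-fold, the mitochondrial protease gene Clpx 3.92-fold and Nampt 2.27-fold. In the list of glycogen and glucose genes 3 of 27 passed (11 over the list alone), in cholesterol synthesis 5 of 26 (18 over the list alone), and in the interferon response 0 of 22 (2 over the list alone). The size of the Liver-RE count depended on the test: a fit of the 18 Liver-RE libraries alone gave 191, the rank test 21 and the F test between 6 harvest times 29. It was 249 without Liver-RE ZT16 replicate 2, 291 without Liver-RE ZT12 replicate 3 and 291 without Liver-RE ZT16 replicate 3, and 729 with quantile normalization. In simulated data 20.7% of the Liver-RE rhythm calls were false with independent genes and 63.7% with whole residual libraries, where 1 set held 1233 false genes and the median set 22.5.

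WT and Liver-RE shared 295 rhythmic genes, 65.7% of the Liver-RE calls and 10.7% of the WT calls, where independent lists would share 105. The number was 195 without Liver-RE ZT16 replicate 2. Over the 170 of these with a peak-to-trough of at least 1.5 in both, the peak came earlier in Liver-RE for 168. The median phase difference was -3.84 h, with quartiles of -5.01 and -2.77 h and a jackknife standard error of 0.946 h over libraries. The median ratio of amplitudes, Liver-RE over WT, was 0.827, with quartiles of 0.708 and 1.06 and a jackknife standard error of 0.132. With 1 library left out it ranged from 0.776, without WT ZT8 replicate 2, to 0.892, without Liver-RE ZT8 replicate 1. The rhythm differed between Liver-RE and WT for 413 genes. Of these, 127 were rhythmic in both, and 258 were rhythmic in WT and not past the threshold in Liver-RE. The smallest p-values belonged to Mpzl1, which peaked at ZT0.28 in WT and ZT17.34 in Liver-RE, and to Tab2, Tef, St5 and Marveld1. Of the 23 clock genes 14 differed (18 adjusted over the list alone). Ciart, Per2 and Per3 were among the next smallest, with Per2 at ZT13.28 in WT and ZT6.63 in Liver-RE. Leaving out WT ZT4 replicate 3 lowered the count of rhythm differences to 260, and leaving out WT ZT8 replicate 2 raised it to 580.

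**Figure D2:**
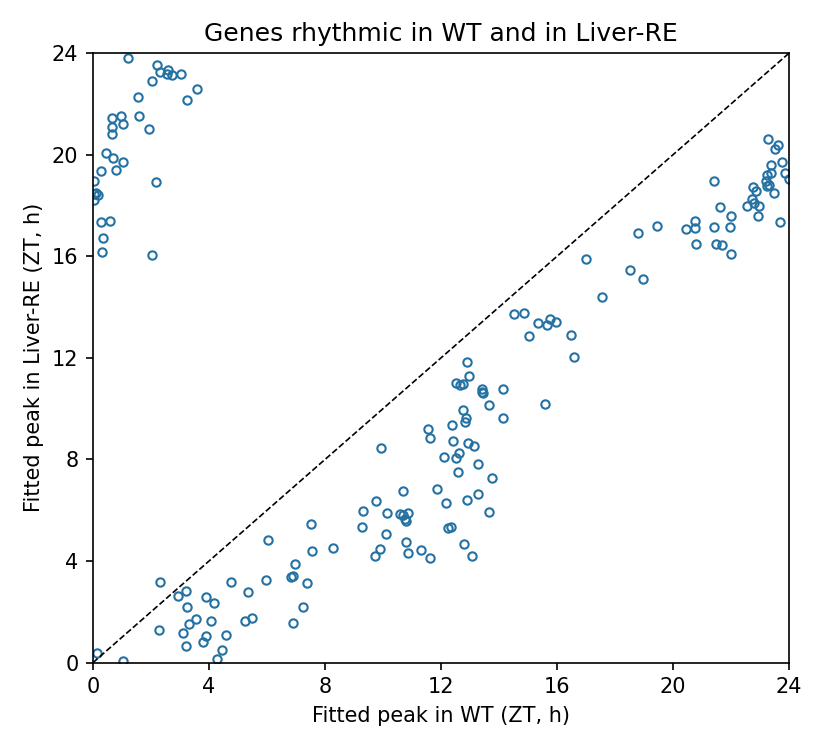
Fitted peak time in Liver-RE against that in WT, both in h (ZT), for the 170 genes rhythmic in both with a peak-to-trough of at least 1.5 in both; each circle is a gene and the dashed line marks equal times. ZT is circular, and counted the shorter way round peaks came earlier in Liver-RE for 168 genes.

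The test of Liver-RE against KO, which asks whether liver BMAL1 changed the rhythm, passed for 28 genes, 27 of them rhythmic in Liver-RE. Of the 23 clock genes 4 passed over all genes and 16 adjusted over the list alone. At an unadjusted p under 0.05 there were 1460. The smallest adjusted p-values were those of Tab2 (5.50e-07), Clpx (0.000672) and Map4k4 (0.00816), followed by Nampt (0.00856), and Cebpa, Per3 and Dbp were also among the 10 smallest. This count moved by more than 1.5 times on leaving out any 1 of 26 libraries. It ranged from 7 without KO ZT8 replicate 3 to 65 without Liver-RE ZT16 replicate 1, and was 7 with no filter and 59 with quantile normalization.

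The second comparison asked how the log2 level averaged over the day differed between KO and WT. Of the 11759 genes, 1940 were higher and 1592 lower in KO, 84 and 95 of them at least 2-fold. The balance of directions depended on the scaling. With the 20 highest genes left out and libraries rescaled, 1654 were higher and 1970 lower, and with quantile normalization 1987 and 1991. The lowest fold changes included those of genes listed as more highly expressed in female liver. Cyp2a4 (chromosome 7, 26307192 to 26315088), a steroid hydroxylase, had a mean of 602 FPKM in WT and 3.85 in KO, log2 fold change -7.01 ± 0.228 (SE, n = 18 per genotype), adjusted p = 9.64e-30. Sult2a1 had -5.81 ± 0.502, Cyp3a44 -4.99 ± 0.370 and Sult2a2, which was not on the female-biased list, -5.18 ± 0.415. Of the 19 measured female-biased genes, 15 were lower in KO and 0 higher, over all genes and adjusted over the list alone; camera gave an adjusted p of 0.00348. Of the 20 measured male-biased genes 10 were higher and 1 lower (11 and 1 over the list alone), with an adjusted p of 0.646 with an estimated correlation. Hsd3b5 rose by a log2 fold change of 3.45 ± 0.412, Elovl3, a fatty acid elongase, by 3.37 ± 0.349, Mup20 by 2.95 ± 0.378 and Cyp2d9 by 2.61 ± 0.277. Other genes at the top were Cyp2c55 (3.56 ± 0.180), Hectd2os (3.53 ± 0.167), Lpl, the lipase that hydrolyses circulating triglycerides (3.33 ± 0.163), and Spink1 (2.97 ± 0.233).

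Clock genes changed in mean log2 level in both directions, which a change in swing alone can also bring about. Of the 23 measured, 9 were higher and 9 lower in KO. The log2 fold change was -2.06 for Nr1d2, -1.48 for Dbp, -1.44 for Nr1d1 and -1.12 for Ciart, while Npas2 (log2 fold change 1.74) and Cry1 (1.31) rose. In the metabolic lists, 10 of 22 fatty acid and triglyceride synthesis genes were lower and 1 higher, with Pnpla3 at -1.50 and Fads2 at -0.86 (adjusted p = 0.487 with an estimated correlation). Of the 26 cholesterol synthesis genes 14 were higher and 0 lower, with Insig2 at 1.07 and Hmgcs1 at 0.90 (adjusted p = 0.796 with an estimated correlation). Insig2 encodes a protein that restrains that pathway. Of the 22 interferon response genes 10 were lower, with Ifit3 at -0.68 (adjusted p = 0.654 with an estimated correlation). Xenobiotic metabolism genes went both ways, 12 higher and 8 lower of 28 (12 and 10 over the list alone), with Gstm3 at 2.36 and Cyp2a5 at -2.72. Of 14 Kupffer cell and macrophage markers 10 were lower, with C1qa at -0.48 (adjusted p = 0.605 with an estimated correlation), beside 10 lower interferon response genes. Among the 15 hepatocyte markers 3 rose and 4 fell (3 and 2 with quantile normalization; median 0.087, mean -0.053), and Alb, the albumin gene, had a log2 fold change of -1.16; its share of the summed values was 10.2% ± 1.20 in WT and 4.82% ± 0.920 in KO (SD, n = 18). Of the 4 measured cholangiocyte markers 3 were higher, Spp1 at 1.00 and Sox9 at 0.71 (adjusted p = 0.0588 with an estimated correlation).

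**Figure D3:**
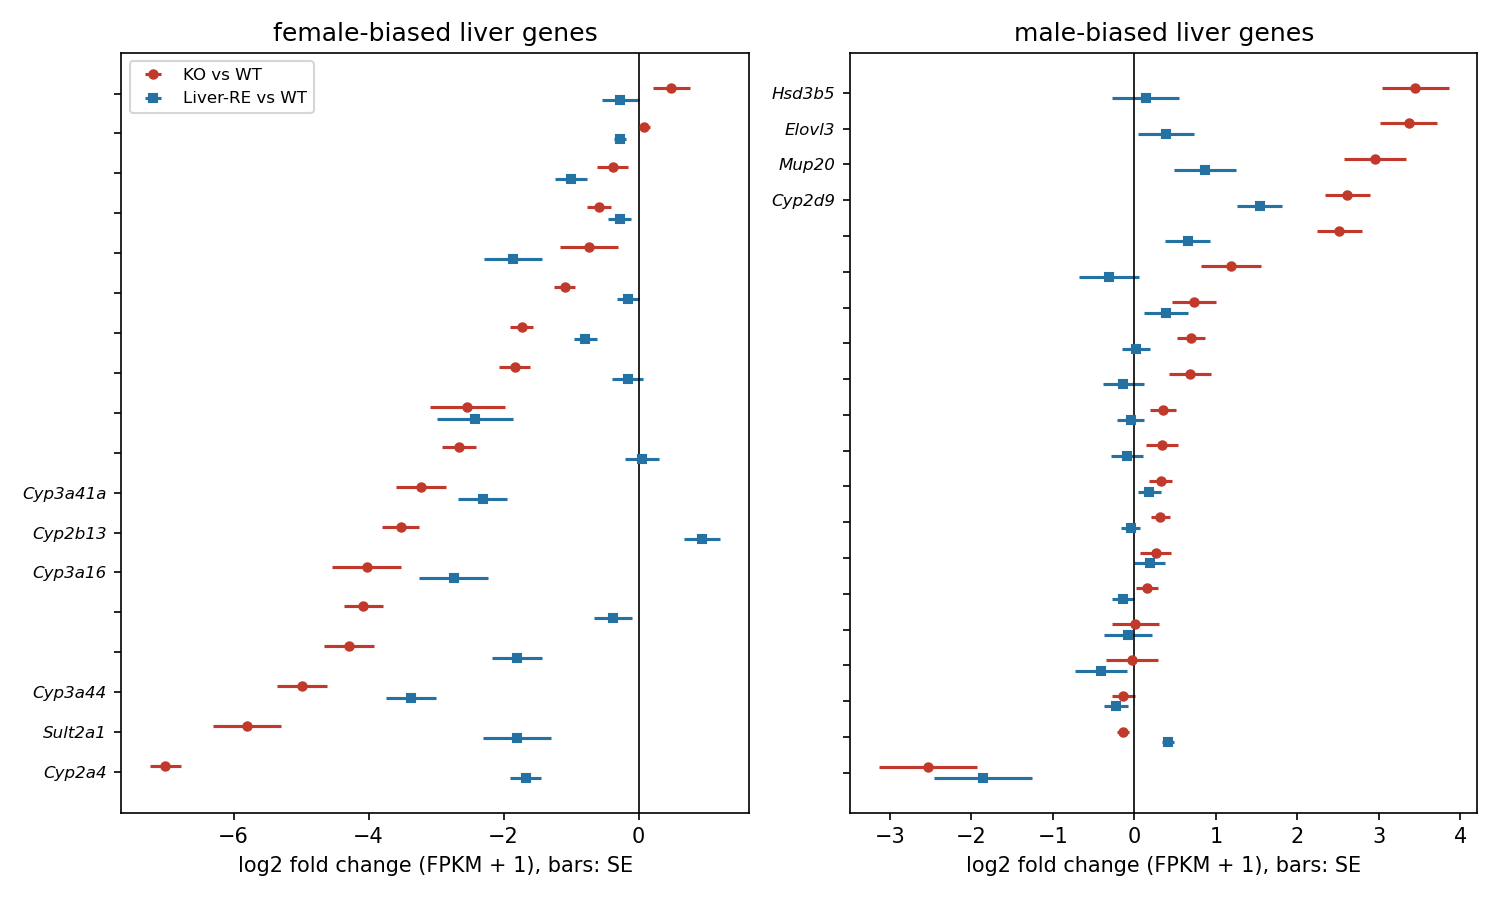
Log2 fold change on the FPKM + 1 scale, with its SE as bars, of 18 of the 19 measured female-biased (left) and the 20 measured male-biased (right) liver genes, in KO vs WT (red circles) and in Liver-RE vs WT (blue squares); only genes named in the text carry a label. Cyp2a4 lay at -7.01 in KO and -1.67 in Liver-RE.

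The third comparison set Liver-RE against WT. Of the 11759 genes 139 were higher and 691 lower in Liver-RE, 6 and 16 of them at least 2-fold. None of the 23 clock genes passed the threshold in level, over all genes or over the list alone. Ciart, for example, had a log2 fold change of -0.34 ± 0.157. Female-biased genes were again among the lowest fold changes: Cyp3a44 at -3.37 ± 0.370, Cyp3a16 at -2.74 ± 0.512, Cyp3a41a at -2.31 ± 0.366 and Cyp2a4 at -1.67 ± 0.228. Of the 19 measured 12 were lower and 1, Cyp2b13, higher, over all genes and adjusted over the list alone (adjusted p = 0.107 with an estimated correlation). Cyp2b13 is named here after its value was seen. Cyp2d9 (1.54 ± 0.277), Cd36, a fatty acid transporter (1.21 ± 0.116), Fitm1, a lipid droplet protein (1.20 ± 0.159), and Mmp9 (1.19 ± 0.107) were the highest of the named genes. Of the 24 fatty acid oxidation and PPAR-alpha genes 5 were higher, with Cyp4a10 at 0.89 (adjusted p = 0.327 with an estimated correlation). Of 14 Kupffer cell and macrophage markers 5 were lower (8 over the list alone), Marco at -1.23 (adjusted p = 0.634 with an estimated correlation). Markers of other cell types fell as well: 2 of 15 liver endothelial (7 over the list alone), with 1 higher, 4 of 14 stellate cell and fibroblast (7 over the list alone), with 2 higher (3 over the list alone), 2 of 15 hepatocyte (5 over the list alone) and 2 of 5 lymphocyte markers (3 over the list alone). Their adjusted p with an estimated correlation was 0.796, 0.971, 0.861 and 0.706, and with quantile normalization 1, 3, 0 and 1 were lower, with 3 stellate markers higher. Beside them 5 of 22 interferon response genes were lower (8 over the list alone), such as Irf7 at -0.50 (adjusted p = 0.722 with an estimated correlation). Of 10 listed adipocyte markers 4 were measured, and 2 were higher (3 over the list alone), Fabp4 at 0.35 and Car3 at 0.52 (adjusted p = 0.00348 with an estimated correlation, here -0.017). Camera sets a list against the other genes, and the median log2 fold change of all genes was -0.057 in this contrast. Whether adipocytes were the source was not tested. The balance of directions followed the scaling: with quantile normalization 247 genes were higher and 266 lower. There were 430 lower genes without Liver-RE ZT8 replicate 1 and 457 without Liver-RE ZT12 replicate 1.

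The fourth comparison, Liver-RE against KO, asked what restoring BMAL1 in the liver changed. There were 873 higher and 3134 lower genes, 78 and 71 of them at least 2-fold; with quantile normalization there were 1457 higher and 1643 lower. Cyp2a4 was higher in Liver-RE by a log2 fold change of 5.34 ± 0.228, Cyp2b13 by 4.46 ± 0.272 and Mme, a membrane peptidase, by 2.88 ± 0.136. Of the 19 female-biased genes 13 were higher and 4 lower, over all genes and over the list alone (adjusted p = 0.0112 with an estimated correlation), and 11 and 1 with quantile normalization. The lowest log2 fold changes included those of Hectd2os (-3.87), Hsd3b5 (-3.31), Elovl3 (-2.98), Loxl4 (-2.93) and Lpl (-2.57). Of the 20 male-biased genes 9 were lower and 1 higher (10 and 1 over the list alone; adjusted p = 0.861 with an estimated correlation). Of 22 fatty acid and triglyceride synthesis genes 14 were higher and 0 lower (15 and 1 over the list alone), among them Scd1, a desaturase, at 1.29, Me1 at 1.21 and Fads2 at 0.98 (adjusted p = 0.0588 with an estimated correlation). Of 24 fatty acid oxidation and PPAR-alpha genes 10 were higher (11 and 1 lower over the list alone), with Ppara at 0.64 (adjusted p = 0.466 with an estimated correlation). Of the 23 clock genes 8 were higher and 9 lower (9 and 8 with quantile normalization), with Nr1d2 at 2.24 and Cry1 at -1.59. Of the 4 measured adipocyte markers 3 were higher, with Pparg at 0.49 (adjusted p = 0.0274 with an estimated correlation). Of the 4 measured cholangiocyte markers 3 were lower, with Spp1 at -1.36 (adjusted p = 0.0516 with an estimated correlation). Over all lists and contrasts, 4 tests passed with an estimated correlation and 28 with a preset one.

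Of the 3532 genes that differed between KO and WT, 2264 (64.1%) changed back in Liver-RE against KO: 1575 were higher in KO and lower in Liver-RE, and 689 were lower in KO and higher in Liver-RE. Independent lists would share 517 and 118. Both contrasts use the same KO libraries. Simulated unchanged WT and Liver-RE groups gave 0 in each of 20 sets, which holds without any effect and does not measure what the shared libraries add beside real ones. With the KO libraries split into 2 sets of 9, one for each contrast, 1262 of 2585 genes (48.8%) changed back. Fewer libraries also let fewer genes pass, so the 2 shares are not measured alike. With quantile normalization 2305 genes changed back. Changed back means a call in the opposite direction, not a return to the WT level. Of the 3532 genes, 455 were still past the threshold in Liver-RE vs WT in the same direction, and 48 in the opposite direction.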

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

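The tests for male mice and for the share of hepatocytes were chosen only after the result was seen.

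Hectd2os, an antisense transcript on chromosome 19 (36619418 to 36689479), differed between KO and WT by an amount that depended on harvest time (limma, test of the rhythm difference, adjusted p = 0.0284). Its peak-to-trough fold was 3.29 in WT and 1.21 in KO. It was the 1 gene, among the highest and lowest named for KO vs WT and for Liver-RE vs WT, whose genotype difference changed over the day. Strand use in the counting is not stated, so whether its reads were separated from those of overlapping genes is not known.

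The pattern weighed first is the shift of sex-biased genes in KO, where 15 of 19 female-biased genes were lower. Male mice among the KO libraries are argued against by Xist, whose lowest KO value was 67.8% of the WT mean. The authors' scaling is argued against because 15 female-biased genes were still lower with quantile normalization. A lower share of hepatocytes is argued against because the hepatocyte markers' median lay 2.74 above that of the female-biased genes on the log2 scale, with a jackknife standard error of 0.367. What stays open, untested, is a biological difference that comes with the genotype, inside or outside the liver: in Liver-RE 13 of the 19 genes were higher and 4 lower than in KO (11 and 1 with quantile normalization; limma camera, adjusted p = 0.0112 with an estimated correlation), and 1 was higher and 12 lower than in WT (adjusted p = 0.107 with an estimated correlation).

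Other groupings of the same libraries were tested with 100 splits each, the real one included. Genotypes were shuffled within harvest times, and for rhythms harvest times within a genotype. For KO vs WT, 1 of 100 splits gave as many higher genes (1940 against at most 764 in the others) and 1 as many lower genes (1592 against 841). For Liver-RE vs WT it was 1 for higher (139 against 6) and 1 for lower genes (691 against 10), and for Liver-RE vs KO 1 for higher (873 against 150) and 1 for lower (3134 against 677). For rhythms, 1 of 100 gave as many in WT (2760 against 597) and 1 in Liver-RE (449 against 33). For the 0 genes in KO all 100 did by construction, the highest being 7, so the splits say nothing of that count. For rhythm differences the number was 1 for KO vs WT (915 against 886), 1 for Liver-RE vs WT (413 against 119) and 3 for Liver-RE vs KO (28 against 117). By these splits chance is argued against for the level contrasts, the rhythms in WT and Liver-RE and the rhythm difference Liver-RE vs WT. It is not excluded, since the share cannot fall below 1 of 100. That does not secure the size of the Liver-RE count: whole residual libraries gave up to 1233 false genes in 1 simulated set, and the rank test called 21 genes and the F test 29. For the rhythm differences KO vs WT and Liver-RE vs KO the margin is narrow, and single omissions moved the latter from 7 to 65 genes. Shuffled genotypes keep the level differences in the data, and an unbalanced split can carry these into the rhythm terms. The splits therefore do not isolate a rhythm difference. What gave 117 genes in another split, several times the real 28, was not tested.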

How the results depend on the processing

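The alternatives were planned, except leaving out 2 libraries together and the preset correlation, which were chosen only after the result was seen. Depth bears on the low genes, where 1 read is a large step.

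With the replicate number as a block, as in a paired design, 2021 genes were higher and 1618 lower in KO than in WT, and 2885 were rhythmic in WT and 501 in Liver-RE; no call changed among the 486 named values. The numbers were not taken to pair the mice, since of 459 pairs of libraries with the same number 34.9% had a correlation of deviations over 0.1. The mean was 0.0397, from -0.402 to 0.510. Deviations sum to 0 within a group, so the mean for different numbers, -0.0201, largely follows from it and is no separate evidence. Of the 54 libraries, 29 correlated best with their own number, a hint of pairing from the data, not the design.

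With quantile normalization, 247 genes were higher and 266 lower in Liver-RE than in WT, 1457 higher and 1643 lower in Liver-RE than in KO, and 2 were rhythmic in KO and 729 in Liver-RE. The rhythm difference Liver-RE vs KO then held 59 genes, against 7 with no filter, 44 with 18 group means, 60 without the 2 libraries with clock genes out of phase (WT ZT8 replicate 2 and Liver-RE ZT20 replicate 1) and 49 with the 36 libraries of the 2 genotypes. Rhythms in KO numbered 2 with no filter, 1 with 18 group means and 1 without those 2 libraries. The 18 Liver-RE libraries alone gave 191 rhythmic genes. The rank test gave 1696 in WT and 21 in Liver-RE, and the F test between harvest times 29 in Liver-RE. A preset correlation of 0.01 gave 28 gene list calls against 4. Quantile normalization fixes the balance of directions by construction, and for the others the cause was not tested.

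With 1 library left out at a time, between 430 (without Liver-RE ZT8 replicate 1; 457 without ZT12 replicate 1) and 964 genes were lower in Liver-RE than in WT. Rhythms in KO ranged from 0 to 3 (KO ZT20 replicate 2), with 1 without WT ZT0 replicate 1, ZT8 replicate 2, ZT16 replicate 2 or ZT20 replicate 3, KO ZT4 replicate 3, ZT8 replicate 2 or any ZT12 replicate, or Liver-RE ZT0 replicate 3, ZT16 replicate 2 or ZT20 replicate 2. Rhythms in Liver-RE ranged from 249 (Liver-RE ZT16 replicate 2; 291 without ZT12 replicate 3 or ZT16 replicate 3) to 645, and genes rhythmic in WT and Liver-RE from 195 (Liver-RE ZT16 replicate 2) to 373. The rhythm difference KO vs WT ranged from 568 (WT ZT12 replicate 3) to 1133 (WT ZT8 replicate 2). That of Liver-RE vs WT ranged from 260 (WT ZT4 replicate 3) to 580 (WT ZT8 replicate 2), and that of Liver-RE vs KO from 7 to 65. The last count was at most 18 without WT ZT12 replicate 3 or ZT20 replicate 3, KO ZT0, ZT4, ZT8, ZT12 or ZT16 replicate 1, KO ZT16 replicate 2 or 3, KO ZT8 or ZT20 replicate 3, Liver-RE ZT0 replicate 1 or 2, ZT4 replicate 1, ZT8 replicate 2, ZT12 replicate 3, ZT16 replicate 2 or 3, or ZT20 replicate 1 or 3. It was at least 43 without WT ZT8 replicate 2 or ZT20 replicate 1, or Liver-RE ZT0 replicate 3, ZT8 replicate 1, ZT12 replicate 2 or ZT16 replicate 1. The median phase difference stayed between -4.32 and -3.52 h.

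Of the 486 named values, the test was no longer passed by 3 with a pseudocount of 0.1, 21 with no filter, 22 with quantile normalization, 4 with 18 group means, 3 with robust empirical Bayes and 21 without the 2 libraries, and in 532 of 26244 single omissions. Those that changed sign were log2 fold changes of clock genes not past the threshold. For Liver-RE vs WT, a pseudocount of 0.1 gave 0.097 for Arntl and 0.16 for Usp2, and quantile normalization 0.037 for Clock, 0.017 for Usp2, 0.032 for Csnk1d and 0.0072 for Fbxl21. Without the 2 libraries, Arntl had 0.16, Clock 0.034, Nr1d1 -0.15 and Nr1d2 -0.059. For Liver-RE vs KO, Per1 had -0.0017 without them. With 1 library left out, Liver-RE vs WT ranged from -0.12 to 0.098 for Arntl, -0.044 to 0.037 for Clock, -0.12 to 0.018 for Usp2 and -0.035 to 0.22 for Nr1d1. Liver-RE vs KO ranged from -0.0017 to 0.12 for Per1, and KO vs WT from -0.00099 to 0.051 for Rora. The cause was not tested.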

Other observations

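The test of gene length was chosen only after the result was seen, and the tests on WT ZT8 replicate 2 after its clock genes had been seen.

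Single genes of other lists also differed in level, while none of the 3 lists given here passed as a group. Of 16 glucocorticoid-responsive genes 6 were lower and 2 higher in KO than in WT, with the metallothionein genes Mt2 at a log2 fold change of -2.36 ± 0.516 and Mt1 at -1.67 ± 0.412 (SE, n = 18), and Fkbp5 at -0.80 ± 0.211 (adjusted p = 0.706 with an estimated correlation). Of 20 acute phase genes 8 were lower and 4 higher in KO (8 and 6 over the list alone), with Orm3 at -1.57, Saa4 at -1.23 and Cp, which encodes ceruloplasmin, at 0.74 (adjusted p = 0.861 with an estimated correlation). Of 19 genes of the unfolded protein and integrated stress response, 7 were lower and 2 higher in Liver-RE than in KO (9 and 2 over the list alone), with the chaperone gene Calr at -0.50 and Trib3 at 0.65 (adjusted p = 0.983 with an estimated correlation). Hspb1, a small heat shock protein gene, was lower than in WT in KO (-1.34 ± 0.154) and in Liver-RE (-0.98 ± 0.154).

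A harvest time was estimated for each library from WT rhythms fitted without that library. From clock list genes the estimate minus the label had a median of -0.40 h in WT and 4.32 h in Liver-RE; from 100 rhythmic genes outside the list the medians were 0.60 h and 3.70 h. In Liver-RE the differences from clock genes ran from -3.6 to 9.4 h, with a median absolute deviation of 2.05 h, and those from other genes from -8.4 to 9.6 h, with 2.65 h. The estimates from other genes lay between ZT4.8 and ZT10.3 whatever the label, except at ZT21.3 for ZT16 replicates 2 and 3, so their median is not a shift common to the libraries. In 5 Liver-RE libraries the estimate from clock genes lay more than 6 h from the label, and in 5 that from other genes.

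In WT ZT8 replicate 2 the clock genes were out of phase with the other libraries of that group. The time estimated from genes outside the clock list lay 11.6 h from ZT8, and that from clock genes 11.5 h; in no other WT library was either over 6 h. A wrong harvest time of this library is a candidate explanation that these values fit, and a mouse whose rhythm was shifted would give the same. A swap with Liver-RE ZT20 replicate 1, whose estimates lay 9.4 and 9.5 h from its label, is argued against, as 0 of these 2 libraries lay nearer to the other genotype on a score of genes that differ between Liver-RE and WT. The library kept its label throughout, and without it 3255 genes were rhythmic in WT.

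Calls in Liver-RE were mostly lower, 83.3% of those against WT. With the 20 highest genes left out and libraries rescaled, the share was 60.8%, with a jackknife standard error of 12.4 percentage points. Those genes held on average 31.2% of the summed values in Liver-RE, 33.0% in WT and 27.9% in KO. Against WT they thus took no larger part of the signal in Liver-RE. The test does not decide, because leaving them out and rescaling to one total were done together. One scale factor per library predicts no trend with gene length. With genes in 5 classes of transcript length, the median log2 fold change Liver-RE vs KO of the shortest class minus that of the longest was -0.057, with a jackknife standard error of 0.029, which does not decide either. A general fall of RNA in Liver-RE and the scaling cannot be told apart here, because values scaled to depth keep no total.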
